A study of Rattus norvegicus with 24 samples.

How the data were processed

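Liver RNA of 12 rats was compared on 24 two-colour microarrays printed with oligonucleotides. Per the labels, 24 rats ate seed that was either free of or infected with a fungal endophyte for 5 days at 21 °C. The 12 animals used for arrays were selected by how strongly they responded, judged from liver weight, feed intake, weight gain and core temperature. Each array carried cDNA of 2 animals, 1 labelled with Cy3 and 1 with Cy5. Each animal was on 4 arrays, 2 in each dye, and these are technical repeats of a single liver. The labels used here name the animals by number and give no diet for any of them, so no diet comparison was made.

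The deposited values are 1 log ratio per probe and array, for 1920 probes. The base is not stated in the sources used here, and base 2 was assumed. If signals are 16-bit and at least 1, decimal logarithms are excluded by 196 values on 21 arrays. Natural logarithms are opposed only by 20 values on 1 array, rat 6 with rat 24, all equal to 14.673, whereas no other value exceeds 8.535 in size. Such a repeated number looks like a cap or a filled-in value, so the base is not settled. Sizes given on the log2 scale hold only for base 2, and tests do not depend on it. The scanner, background correction and normalization are not given in the sources used here, and neither is whether a ratio is Cy5 over Cy3 or the reverse. Levels are therefore given as if each ratio were Cy5 over Cy3, and every sign would turn together otherwise. F-tests, correlations between genes and sizes do not depend on that choice. No intensities were used, so the signal behind a ratio is unknown, and the number of arrays limits the precision.

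The authors' centring is also unknown. The deposited array medians, on the log2 scale and named by the animal in Cy3 and then the animal in Cy5, were −0.047 for 13 with 6, −0.0415 for 13 with 29, −0.02 for 16 with 5, −0.033 for 16 with 6, 0.0655 for 17 with 19 and −0.01 for 17 with 29. They were −0.0905 for 19 with 23, −0.216 for 19 with 9, 0.158 for 23 with 5, 0.0725 for 23 with 8, 0.0025 for 24 with 19 and 0.019 for 24 with 25. They were −0.0325 for 25 with 16, 0.0405 for 25 with 23, 0.181 for 29 with 24, 0.016 for 29 with 9, −0.102 for 5 with 13 and −0.007 for 5 with 17. The last group had 0.118 for 6 with 24, −0.856 for 6 with 17, 0.002 for 8 with 13, 0.087 for 8 with 16, −0.037 for 9 with 8 and −0.036 for 9 with 25. Each array was centred on its median before the fit.

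Gene names came from the platform annotation supplied with the values. It gave 1 name to 1083 probes, several names to 7 and none to 830. The named probes covered 1019 genes, of which 1008 were found by gene ID in a RefSeq gene table of assembly GRCr8, used for names only. No probe with several names was named. Missing values made up 9.80% of the table, 2.27% of the probes with 1 name and 19.7% of the unnamed probes.

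A linear model with 11 free animal effects and a dye term per probe was fitted by limma to the arrays. Probes with at least 20 of 24 values and an estimable model entered, which left 1491 probes, 1049 of them with 1 name and 435 unnamed. Animal differences were tested with limma's moderated F-test and Benjamini-Hochberg adjustment at 0.05. For gene groups, probes of a gene were averaged, which left 986 genes. An animal's level is its fitted effect against the mean of the 12 animals, with a standard error (SE) from array error. This SE is averaged over the animals, so it is the same for every animal of a probe.

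The array titles define 2 sets of animals. Of the 462 ways to split the 12 animals into 6 and 6, exactly 1 puts the 2 animals of every array in different sets, and any other split does so for at most 18 of the 24 arrays. Set A held rats 9, 13, 16, 17, 23 and 24, and set B held rats 5, 6, 8, 19, 25 and 29. The labels do not say what separates the sets. The set difference is B minus A, tested by limma on the 12 animal levels, with the animal as the replicate.

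Before the data were examined, 24 gene lists, the tests, 8 pairs of lists and the rule for named genes were fixed. The rule took probes with 1 name. For animal differences it took the 20 past the threshold with the largest standard deviation (SD) over animals, and up to 3 per list. For the set difference it took the 20 largest past the threshold, filled by smallest p with probes that did not pass. Other genes named below were chosen after their values were seen. They passed adjustment over their list alone or after averaging, or are named for the correlation between their probes or as held-out genes. Lists with at least 5 measured genes, 18 of the 24, were tested with camera at its preset correlation, Fisher's exact test on calls, and mean pairwise correlation against 10000 random lists. Correlations between list means used 100000 permutations. No list test was run for dopamine, serotonin and adrenergic receptors with 2 genes measured, circadian clock genes with 3, stellate cells and matrix with 4, endothelial and bile duct cells with 3, erythroid genes with 1 and non-liver tissue markers with 4.

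The procedure was tested on simulated data with the residual spread of each probe, the layout and the missing values, and 200 changed probes among 1491. Simulated error had equal spread on all arrays and was independent between probes. The measured arrays differed, with an SD over probes with 1 name from 0.326 (16 with 6) to 1.36 (6 with 17). Recovery and error rates in the measured arrays may therefore differ. For animal effects with an SD of 0.5 it recovered 49.0% of changed probes, and for an SD of 1 it recovered 92.5%. For set differences of 0.5 with an SD of 0.2 between animals it recovered 0%, and for differences of 1 it recovered 91.0%.

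Alternatives covered centring, scaling of arrays, the dye term, missing values, robust fitting, averaging over probes, other list tests, and leaving out each animal or array. A left-out animal left 20 arrays, of which 17 values were then required. Setting the 20 repeated values to missing, removing a pair of nearly identical arrays, restricting to named probes, weighting arrays, the exact permutation of list means, which treats all splits of the animals alike although the layout does not, and Fisher's test on unadjusted calls were added after seeing the data. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.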

Results

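Hepatic transcripts of 12 rats from a study of fescue toxicosis, a disorder of animals that eat endophyte-infected tall fescue, were measured on 24 arrays. Each array compared an animal of set A with an animal of set B. As the labels used here give no diet per animal, the data were asked whether livers of individual rats differed beyond array error, and whether the 2 sets differed.

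Both arrays with rat 9 in Cy3, against rat 8 and against rat 25, held nearly the same values. Of 1726 probes measured on both, 66.6% were equal within 0.002 and 204 were identical, with r = 0.866 across probes. In no other pair of the 276 pairs of arrays were more than 0.776% of probes equal within 0.002. At least 1 of these labels is therefore in doubt. All 24 arrays were kept as designed, and the main counts are also given without these 2 arrays. The SE takes them as separate repeats, so for rat 9 it may be too small. If 1 hybridisation lies behind both labels, the level of rat 8 or of rat 25 rests partly on a ratio from another animal. Levels of rats 8 and 25 given below carry that doubt, and the error estimate behind every test may be affected.

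**Figure D1:**
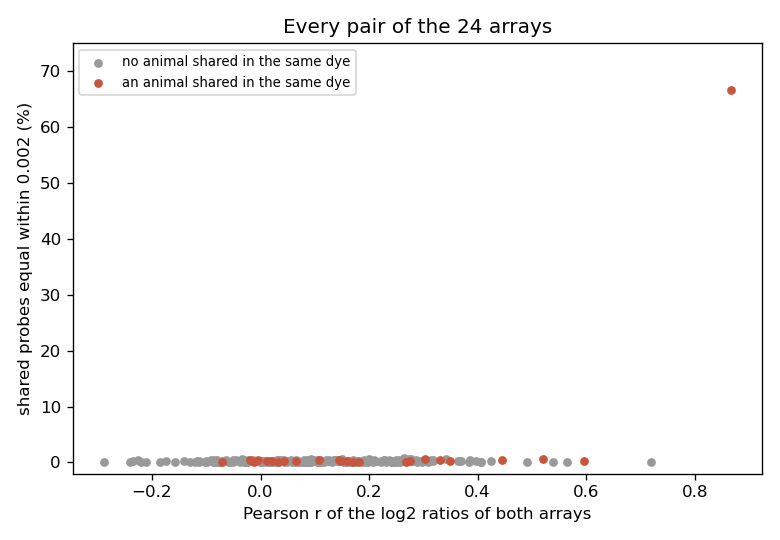
Each point is a pair of the 24 arrays, with the Pearson r of their log2 ratios on the x axis and the percentage of shared probes equal within 0.002 on the y axis. The pair with rat 9 in Cy3 lies at 66.6%, and every other pair at 0.776% or less.

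Livers of individual rats differed most clearly in Pck1, Mt1 and Sult2a2. Pck1, which encodes the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis, spanned 1.79 on the log2 scale, with base 2 assumed for this and all sizes below. Its level was lowest in rat 24, at −1.24 ± 0.19 (SE), and highest in rat 6, at 0.56 ± 0.19, with adjusted p = 0.0289 by limma. Mt1, a metal-binding metallothionein, spanned 3.20, from −2.25 ± 0.33 in rat 9 and −1.50 in rat 29 to 0.95 in rat 25, with adjusted p = 0.0392. Sult2a2, a hydroxysteroid sulfotransferase, spanned 2.35, from −1.11 ± 0.30 in rat 9 to 1.24 in rat 13, with adjusted p = 0.0415. With 1 unnamed probe these made 4 of 1491 probes past the threshold. Without the 2 rat 9 arrays 0 probes passed, with a smallest adjusted p of 0.0513 by limma. At an unadjusted p under 0.05 there were 206 probes (13.8%), against 75 expected by chance, and 166 without those arrays. With arrays reassigned at random the median count was 67 and the highest 167. Without the 2 rat 9 arrays these were 66 and 185, so the highest exceeded the real count. The count past the threshold was also 0 when any of 9 of the 12 animals was left out.

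After probes of a gene were averaged, 10 of 986 genes passed by limma, and 9 without the 2 rat 9 arrays, with 5 genes past in both. Those 5 were Pck1, Mt1, Sult2a2, Sult2a6 and Car3. Sult2a6, a related sulfotransferase, had an SD of 1.12 over animals and ranged from −1.89 in rat 16 to 1.29 in rat 23. Car3, a carbonic anhydrase abundant in liver, had an SD of 0.80 and ranged from −1.42 in rat 24 to 1.14 in rat 16. The other genes past the threshold with all arrays were Cyp3a18, Oaz1, Parp1, RT1-DMb and Hba-a3. The antigen-presentation gene RT1-DMb and the antizyme gene Oaz1 had their extreme level in rat 9, at −1.41 and 2.25, and did not pass without its 2 doubted arrays, with adjusted p = 0.1004 and 0.2003.

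**Figure D2:**
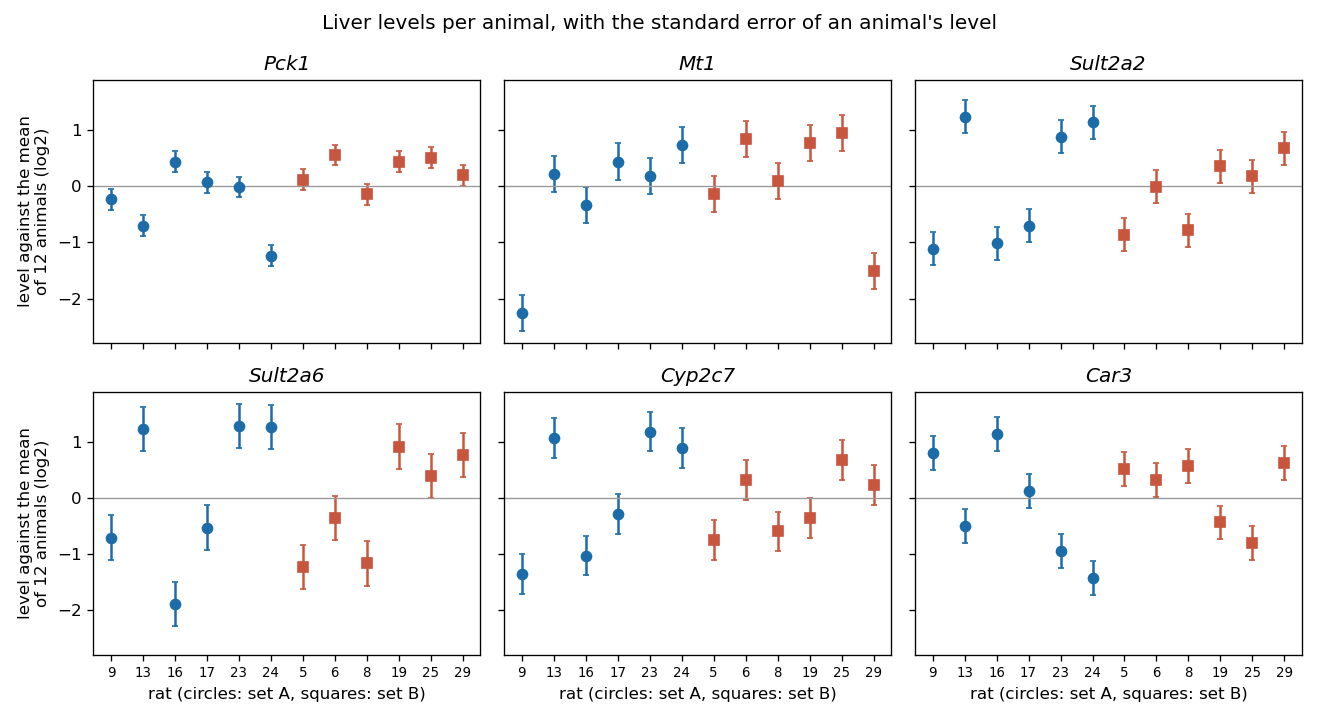
Points give the level of 6 genes in each of 12 rats on a log2 scale against the mean of all animals. Bars give the standard error from array error, averaged over animals, with circles for set A and squares for set B. Pck1 was lowest in rat 24 at −1.24, and Mt1 in rat 9 at −2.25.

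Some genes of hepatic glucose output varied between animals. Adjusted over the list alone, 6 of 19 measured members passed the F-test, and 1 passed over all genes, or 2 without the 2 rat 9 arrays. They were Pck1, the serine dehydratase Sds, the cortisone reductase Hsd11b1, the tryptophan dioxygenase Tdo2, the transcription factor Cebpb and the tyrosine aminotransferase Tat. Of these, Sds, Tdo2 and Tat also belong to the list of urea cycle and amino acid genes. Sds was highest in rat 19, at 1.62 ± 0.26, and Hsd11b1 was lowest in rat 23, at −1.45 ± 0.31. At an unadjusted p under 0.05 there were 8 members, and Fisher's exact test against other genes gave adjusted p = 0.0372, or 0.00639 without the 2 rat 9 arrays. Without those arrays 6 members again passed adjusted over the list alone, with the glucose phosphatase G6pc1 in place of Tat. The Fisher test on unadjusted calls was chosen after seeing the data. Here and below it treats genes as independent, so its p may be too small. Of all 986 genes, 13.9% had an unadjusted p under 0.05 by the F-test with all arrays. With calls past the adjusted threshold, as planned, no list of the 18 stood out, with adjusted p = 1 for each. Only 10 of 986 genes were such calls, so here and below the planned Fisher test had little power and does not argue against a list.

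Some drug-metabolising enzymes varied as well. Of 34 phase 1 enzymes, 6 passed adjusted over the list alone and 1 over all genes. Cyp3a18, a cytochrome P450 of steroid and drug oxidation, ranged from −1.63 ± 0.26 in rat 24 to 1.32 in rat 8. Cyp2c7 ranged from −1.36 ± 0.35 in rat 9 to 1.18 in rat 23. The carboxylesterase Ces1d, Cyp2c12, Cyp2c13 and the quinone reductase Nqo1 were the rest. At an unadjusted p under 0.05 there were 11 members, with adjusted p = 0.0372 by Fisher's exact test, or 0.0161 without the 2 rat 9 arrays. Of 32 conjugation and export genes, 4 passed adjusted over the list alone (Sult2a6, Gsta2, Ugt1a1 and Slco1a4) and 1 over all genes. Their 9 unadjusted calls gave adjusted p = 0.193 by Fisher's exact test, or 0.0258 without the 2 rat 9 arrays. The planned Fisher test on adjusted calls gave adjusted p = 1 for both lists. Without the 2 rat 9 arrays the members past adjusted over the list alone were 4 for phase 1 and 1 for conjugation, with 1 of each past over all genes. For phase 1 that 1 was Cyp2c7, with adjusted p = 0.0433, and Cyp3a18, the 1 with all arrays, did not pass, with adjusted p = 0.0650.

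Bile acid genes had 4 of 18 members past adjusted over the list alone and 0 over all genes. These were the bile acid ligase Slc27a5, the conjugating enzyme Baat and the uptake carriers Slc10a1 and Slco1a4. Slc27a5 and Slc10a1 were lowest in rat 24, at −1.29 ± 0.25 and −0.85 ± 0.20. Of 36 urea cycle and amino acid genes, Arg1, Sds and Tdo2 passed adjusted over the list alone and 0 over all genes. Without the 2 rat 9 arrays 3 bile acid genes and 1 urea cycle gene passed over the list alone, and the latter, Sds, also over all genes. Single members passed over their list alone among antioxidant genes (Mt1 of 26), cholesterol and lipoprotein genes (Fdps of 24), circadian genes (Alas1 of 3), lymphocyte and antigen-presentation genes (RT1-DMb of 7) and erythroid genes (Hba-a1, the 1 measured). No member passed in the lists of glycolysis and fatty acid synthesis (19 genes), fatty acid oxidation (34), oxidative phosphorylation (23), heat shock and ER stress (25), proteasome (31), ribosome and translation (58), acute phase and plasma proteins (40), the growth hormone axis (11), the cell cycle (11) or myeloid cells (11). Without the 2 rat 9 arrays Alas1 no longer passed over its list, and Acly passed over the list of glycolysis and fatty acid synthesis.

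Between sets, no gene differed past the threshold. By limma 0 of 1491 probes passed, and 32 (2.15%) had an unadjusted p under 0.05, of which 14 were higher in set B and 18 in set A. Without the 2 rat 9 arrays 0 passed and 24 had an unadjusted p under 0.05. In simulated arrays without a set difference, and with error of equal spread on all arrays, the layout made this test conservative. There 0.567% of probes reached an unadjusted p under 0.05 with no spread between animals, and 1.34% with an SD of 0.2. Larger spreads were not simulated for the sets. The median size of the difference was 0.10 with a median SE of 0.18. The values with the smallest p, none of which passed, were led by alpha globin. Hba-a3 differed by −0.99 ± 0.27 (SE) and 3 of 4 Hba-a1 probes by −0.80, −0.70 and −0.65, that is, towards set A. The arginase Arg1 differed by 0.69 ± 0.23, haptoglobin (Hp) by 0.49 ± 0.16, RT1-DMb by 0.70 ± 0.26, Tdo2 by 0.41 ± 0.15 and Pck1 by 0.56 ± 0.25, towards set B. Also towards set B were Serpina3n at 0.46, the bile acid carrier Slc10a1 at 0.40, Prkab1 at 0.38, Pmpcb at 0.36 and Kng2l1 at 0.32. Towards set A were Dbi at −0.52, Psma1 at −0.47, Ssbp3 at −0.43, Ptgis at −0.36, Rab7a at −0.33 and Cyp2b12 at −0.31. Ssbp3 fell to −0.27 without the 2 rat 9 arrays. The sets are named by hybridisation layout alone, and these values carry no diet.

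As groups, 3 lists passed between sets by camera at its preset correlation, all towards set B, and 0 passed with an estimated correlation. Bile acid, urea cycle and glucose output genes had adjusted p = 0.0120, 0.0120 and 0.0336 at the preset correlation, and adjusted p = 0.274, 0.339 and 0.274 with an estimated correlation. An exact permutation of the animals on the list means gave adjusted p = 0.577, 0.721 and 0.577. Their median differences were small, at 0.10, 0.06 and 0.07. Without rat 24 the adjusted p was 0.0639 for each, and without the 2 rat 9 arrays only the bile acid list passed, with adjusted p = 0.0291. The alpha globin probes differed in the opposite direction to these lists. Glucose output and urea cycle lists share members, among them Sds, Tdo2 and Tat, so these 2 lists are not separate findings.

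Ribosomal, acute phase and urea cycle genes were each correlated over the animal levels beyond random lists. The first 2 lists were also correlated in array error, and for the third this was not excluded. The mean pairwise r was 0.202 over 58 ribosomal and translation genes, 0.209 over 40 plasma protein genes and 0.122 over 36 urea cycle genes. Random lists of the same sizes had medians of 0.0278, 0.0272 and 0.0270. The adjusted p was 0.0009 for ribosomal and plasma protein genes, from the smallest p that 10000 lists can give, and 0.0078 for urea cycle genes. Genes are not independent replicates. In the array residuals, from which animal effects had been removed, the mean r was 0.204, 0.177 and 0.0688. Random lists had medians of 0.0230, 0.0217 and 0.0221 there. Over genes with complete residuals the ribosomal and plasma protein lists again passed, with adjusted p = 0.0009 for each, and the urea cycle list did not, with adjusted p = 0.159. The co-variation of the first 2 lists is therefore not shown to belong to the animals. For the urea cycle list the failed adjustment does not show that array error was uncorrelated. Without the 2 rat 9 arrays the urea cycle list had r = 0.0886 and adjusted p = 0.0624. The other 15 lists did not pass.

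Of 8 pairs of lists, none correlated past the adjusted threshold over the 12 animals, with or without the 2 rat 9 arrays. Phase 1 enzymes and conjugation genes had r = 0.724 (permutation p = 0.00935, adjusted p = 0.0504) and rho = 0.615 (permutation p = 0.0363, adjusted p = 0.194). Ribosomal and oxidative phosphorylation genes had r = 0.698 (permutation p = 0.0126, adjusted p = 0.0504) and rho = 0.587 (permutation p = 0.0485, adjusted p = 0.194). Without the 2 animals farthest from the median r was 0.714 and 0.695. Within set A it was 0.726 and 0.847, and within set B 0.692 and 0.763. The other 6 pairs had r between −0.0808 and 0.421.

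The first 3 principal components of the animal levels held 17.98%, 15.4% and 13.8% of the variance. On the first, rat 6 lay lowest at −10.3 and rat 24 highest at 12.3, and the sets overlapped. Rats 6 and 24 were paired on 1 array. On the second, rat 6 lay lowest at −9.19 and rat 17 highest at 13.0, and these were paired on the array with the most missing values, 446. Animal levels include array error, so these ends are not shown to be differences between livers. Among 38 genes with several probes, the median r between probes over animals was 0.392, against 0.0266 for random pairs. The probes of Hba-a1 had a median r of 0.965 and those of Cyp2e1 0.913, whereas those of Csnk1a1 had −0.559.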

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

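The tests of the rat 9 arrays, of blood content, of splits in simulated arrays, of the size of list differences without an animal and of reassigned arrays with all 24 arrays were chosen after their results had been seen in part. Among 80 groups of 6 animals examined for an animal far from the rest, 5 stood out, where chance gives about 4. Mt1 in rat 9 was −2.25, with the nearest animal of set A at −0.33. RT1-DMb in rat 9 was −1.41, with the nearest at −0.43. Both rest partly on the doubted arrays. Pmpcb in rat 6 was 0.57, with the nearest animal of set B at 0.19. The mean of the glucose output list in rat 6 was 0.26, with the nearest at 0.07, and the mean of the proteasome list in rat 13 was 0.16, with the nearest animal of set A at 0.03.

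The near identity of both arrays with rat 9 in Cy3 may come from 1 hybridisation deposited under 2 labels, as 66.6% of probes were equal within 0.002, against at most 0.776% in other pairs. Likeness from the shared animal is argued against. Among the other 23 pairs that share an animal in the same dye, the highest share was 0.606%, and the median r was 0.148. Their highest r was 0.595. The highest r of any other pair was 0.720, between 13 with 6 and 6 with 17, where rat 6 changed dye. An effect of rat 6 would lower r there, so a high r alone does not mark a shared animal. Which label is wrong stays open, and no biological explanation was tested.

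For the shift of glucose output, urea cycle and bile acid genes between sets, 9 of 100 splits of the 12 animals, the real one included, gave at least 3 lists past the threshold, and the highest other split gave 5. Other splits carry array error differently, so this count neither excludes nor shows chance. Dependence on 1 animal stays open. Without rat 24, 0 of the 3 lists passed, but their mean differences of 0.12, 0.12 and 0.08 (glucose output, bile acid and urea cycle) fell to 0.09, 0.06 and 0.05 and did not end. Without rat 9, 1 of the 3 passed, and the mean differences were 0.09, 0.12 and 0.03. A different share of blood could not be excluded, because the 3 lists moved by 0.09 ± 0.07 (SE), plasma protein genes by 0.04 ± 0.10, and the difference was 0.704 SE. Diet is not known per animal, so no biological explanation was tested.

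For single probes, 88 of 100 splits gave at least as many at an unadjusted p under 0.05 as the real sets, with 32 for the real sets and 207 for the highest other, but this rank was fixed by the layout and decides nothing. In simulated arrays without a set difference and with an SD of 0.2 between animals, the real sets gave 1.34% of probes and the other splits 4.73% on average, over 20 runs. The real sets gave 2.15% in the measured data. Simulations that treat probes as independent and arrays as equal in spread gave 0.567% with no spread between animals and 1.34% with an SD of 0.2. That rate rose with the spread, and larger spreads were not simulated for the sets. The 2.15% is therefore not shown to exceed what arises without a difference. For animal differences, 1 of 100 assignments of the arrays, the real one, gave as many as 206 probes, and the highest other gave 167. That count decides nothing, because the nearly identical arrays share rat 9 only as labelled and are mostly parted by reassignment. Without the 2 rat 9 arrays 4 of 100, the real one included, gave at least 166, and the highest other gave 185. That share lay under the threshold of 0.05 set beforehand, but only narrowly. With 100 assignments the share is imprecise, and reassignment treats arrays of unequal spread alike. It argues against chance only weakly and does not exclude it.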

How the results depend on the processing

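Restriction to named probes, removal of the 2 rat 9 arrays, array weights, exact permutation of list means, unadjusted calls, array residuals, scaling in the camera test and removal of a repeated value were chosen after seeing the data. The count of 4 probes that differed between animals depended on nearly every setting. It was 1 without centring and with at least 16 values, 0 without the dye term and without the 2 rat 9 arrays, 9 with named probes only, 10 after averaging probes, 17 with complete probes and 28 with scaled arrays. A smaller set of tested probes may account for part of the rise with named or complete probes, but no cause was tested. Array weights gave 89, from an estimate that stopped before convergence. Robust regression gave 980, but on 5 random reassignments of arrays it gave 492 to 804, so its calls are not usable. With single animals left out the count ran from 0 to 4 and was 0 for 9 of 12 animals. With single arrays left out it ran from 0 to 25, the highest without rat 19 with rat 23, and was 0 for 12 of 24.

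The set difference stayed at 0 probes in all settings but arrays as replicates, a test within arrays, which gave 14 and leaves out the spread between animals. A test without variance moderation gave 0, with 38 probes at an unadjusted p under 0.05, against 32 by limma. The 3 lists that differed between sets became 0 with an estimated correlation, 0 with fry, 0 by exact permutation, 1 without the 2 rat 9 arrays and 5 with scaled arrays, and from 0 to 6 with single animals left out (0 without rat 24, 1 without rat 9, 6 without rat 8). Lists enriched in animal differences went from 0 to 2 with unadjusted calls, and to 3 without the 2 rat 9 arrays as well. Co-varying lists went from 3 to 5 with scaled arrays. Correlated list pairs went from 0 to 1 without rat 6 or rat 23. The cause was not tested. None of the 20 probes named for the set difference changed sign in the settings that gave it a value. Averaging over probes gave none, and Ssbp3 had none with complete probes or without rat 8, 9, 16, 19, 24 or 29. As these 20 probes were chosen by p in the same arrays, stable signs were nearly assured and do not show real differences. The direction of other named genes was not followed. Signal over background is unknown, so dim probes could not be set apart. With 20 equal values on 1 array set to missing, 4 probes differed between animals and 0 between sets.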

Other observations

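All tests in this part other than those of held-out genes and array residuals were chosen after the values were seen. Sult2a2, Sult2a6 and Cyp2c7 shared a profile over the 12 animals, with a mean pairwise r of 0.891. All 3 were high in rats 13, 23 and 24 and low in rats 5, 8, 9 and 16. Car3 ran the other way, with r = −0.835 to the mean profile of the 3 over the 12 animals. It was at −0.49, −0.94 and −1.42 in rats 13, 23 and 24, and at 0.52, 0.56, 0.80 and 1.14 in rats 5, 8, 9 and 16. The profile crossed the sets, as rats 13, 9 and 16 all belong to set A.

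A shared programme of sex- and growth-hormone-dependent liver genes was a candidate explanation for that profile, and the test did not decide it. Over 8 measured of 9 held-out genes the mean signed r with the profile was 0.141 (permutation p = 0.256, one-sided), and 2 of the 8 varied between animals at an unadjusted p under 0.05. Those 2, Cyp2c12 and Cyp2c13, had been seen to vary between animals before the test, though not how. Over the 4 genes outside the Cyp2c and Sult families it was −0.0513 (permutation p = 0.593), but none of the 4 varied between animals beyond array error, with a lowest unadjusted p of 0.149 by limma. A value near 0 could then arise under either explanation, so cross-hybridisation between paralogs stays open for Sult2a2 with Sult2a6. It would not by itself join Cyp2c7, a gene of another family, whose r with the mean profile of the 3 was 0.946. That argues against it as the only source of the profile. Array error stays open as well. The mean r between animals exceeded that between array residuals by 0.324, but the 3 genes were chosen for running together over animals, which favours such a gap, and the residual r of 0.567 was high. What drives the profile stays open.

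Animal levels predicted a left-out array only weakly. Each array was predicted from the animal levels of the other 23, without the dye term. The correlation of predicted and measured ratios across probes ran from −0.377 to 0.440, with a median of 0.0773. The lowest was the array of rat 6 with rat 17, which also had the median farthest from 0, at −0.856, and the most missing values, 446. Dye effects stayed in the measured ratios and could lower these correlations, so they do not measure reproducibility alone. Both rat 9 arrays, at 0.281 and 0.357, could also predict each other.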
